A study of Mus musculus with 82 samples.

How the data were processed

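RNA was measured in 82 libraries of ovalbumin-specific mouse T cells, OT-I cells (CD8) and OT-II cells (CD4), which were transferred into recipient mice and recovered by fluorescence-activated cell sorting from pooled spleen and lymph nodes. Per the labels' protocols, recipients were given saline, 5 µg of plain ovalbumin (OVA) or pGal-OVA, a synthetically glycosylated form of the same antigen, and cells were collected 4 days later. The amount of pGal-OVA is given as 5 µg in the series' design text and as the molar antigen equivalent of the OVA in the treatment protocol, so whether both groups had the same amount of antigen is open. In the prophylactic experiment the antigen followed the transfer by 1 day, each library came from 3 pooled mice, cells were sorted into Trizol, and the labels name 2 batches. In the therapeutic experiment the mice were first immunized with ovalbumin in complete Freund's adjuvant and treated a month later, each library came from 1 mouse, and cells were sorted into buffer and snap frozen. Complementary DNA was made with the SmartSeq version 4 chemistry and sequenced as paired 150-base reads.

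The deposited files are 3 tables of estimated counts per protein-coding gene, which the authors made with kallisto 0.46.1 after bcl2fastq on GRCm38, per the submitters' processing notes. How transcript estimates were summed to genes and rounded is not given in the sources used here. The prophylactic tables hold 21900 genes and the therapeutic one has 21823, all of them shared. The other 77 genes were left out of every fit, and count only toward the library totals and genes detected. Of the 21823 shared identifiers, 21806 are in GENCODE M21, which gave the coordinates. Symbols written as calendar dates (27) were all matched to genes through their identifiers.

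Libraries were grouped by experiment, cell type and treatment as labelled. For each experiment and cell type 3 contrasts were fitted: pGal against OVA, pGal against saline and OVA against saline. Counts were filtered with filterByExpr, scaled with TMM factors and fitted with the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fits of the prophylactic libraries carried a term for the batch. Interaction terms tested whether the difference between pGal and OVA itself differed between OT-I and OT-II cells, or between the experiments within a cell type. The contrasts, tests, lists and rule for named genes were fixed before the data were examined.

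Named genes were chosen by rule. In pGal against OVA, the 6 genes with the highest and the 6 with the lowest log2 fold change were named, among called genes with at least 10 counts per M (CPM) in the higher group; against saline, 3 and 3. A panel of Pdcd1, Lag3, Ctla4, Havcr2, Tigit, Tox, Gzmb, Ifng, Mki67, Tcf7, Il7r and Foxp3 was added, with up to 4 called members of each list, Cd4, Cd8a and Cd8b1 as a check of the labels, and 5 genes per interaction. Where no gene was called, the 3 with the smallest p were named. Values per group are normalized CPM, given as mean ± SD over libraries. The text gives a part of these genes.

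There were 25 gene lists with 417 different genes, of which 1 was not in the tables. They covered inhibitory receptors and exhaustion, anergy, cytotoxic effector, naive and memory, proliferation, interferon-stimulated, regulatory T cell, T follicular helper, T helper 1, T helper 2 and T helper 17, T cell receptor early response, apoptosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, homing and adhesion, heat shock and sorting stress, and mitochondrially encoded genes, and markers of B cells, myeloid cells, erythroid cells and platelets, NK cells, the CD4 lineage, the CD8 lineage and stroma. Each was tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, whose directional test asks whether genes move one way on balance and whose mixed test asks whether they change in either direction. Adjustment was over the 25 lists of a contrast. Member genes were also counted with the p-values adjusted over the list alone.

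The depth behind each value is the total of estimated counts, 21.2 to 68.2 M in the 29 prophylactic libraries and 22.6 to 62.5 M in the 53 therapeutic ones. Amplified reads without molecular identifiers are not independent molecules, so depth alone does not give the precision, and spread between libraries was used. The fits were tested on simulated data, drawn from negative binomial distributions with the means, library sizes and dispersions of these libraries and with 66 or 67 genes changed per fold size. For pGal against OVA edgeR recovered 61.2% of 2-fold changes in prophylactic OT-I cells (13802 genes tested), 40.3% in prophylactic OT-II cells (14128 genes), 26.9% in therapeutic OT-I cells (14581 genes) and 19.4% in therapeutic OT-II cells (14244 genes), the last 2 with the libraries defined next. At 4-fold the shares were 84.8%, 71.2%, 74.2% and 59.1%.

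In 11 therapeutic libraries the lineage genes Cd4 and Cd8a were those of the other cell type. No library was reassigned. Each therapeutic contrast was run on all libraries as labelled and on the 42 whose lineage genes match the label, called matching libraries, a choice made after the data were seen. Also added after the data were seen were fits without 5 prophylactic libraries rich in B cell transcripts (mean log2 CPM of the B cell list over 2 above the median of their experiment and cell type) and without 9 therapeutic libraries with over 18000 genes detected or over 5% mitochondrial counts. No saline library was among these 9. Alternatives set beforehand were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts, a replicate block, each batch alone, and leaving out each library in turn. For every contrast, other splits of the same libraries into groups of the same sizes were fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out of the labelled comparisons.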

Results

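Expression of protein-coding genes was measured in 82 libraries of transferred T cells that recognize ovalbumin: OT-I cells are CD8 T cells and OT-II cells are CD4 T cells. Recipients were given saline, plain OVA or pGal-OVA, here called pGal. The prophylactic experiment had 5 libraries per treatment of OT-I cells, and 4 OVA, 5 pGal and 5 saline libraries of OT-II cells. The therapeutic experiment, in mice immunized a month earlier, had 10 OVA, 10 pGal and 8 saline libraries of OT-I cells and 8, 10 and 7 of OT-II cells. Total counts per library are given in M (mega). In prophylactic OT-I libraries they were 33.5 to 63.9 M after OVA, 36.5 to 63.8 M after pGal and 53.9 to 68.2 M after saline. In prophylactic OT-II libraries they were 33.2 to 62.1, 21.2 to 51.4 and 32.9 to 57.4 M. In therapeutic OT-I libraries the totals were 27.7 to 50.1, 29.8 to 56.7 and 24.7 to 62.5 M, and in therapeutic OT-II libraries 25.2 to 57.3, 22.6 to 62.3 and 32.2 to 58.0 M.

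Cd4 and Cd8a, which encode the coreceptors of the CD4 and CD8 lineages, served as a check of the cell type labels. In the 15 prophylactic libraries labelled OT-I, Cd8a lay between 786 and 1173 CPM and Cd4 between 0.326 and 197 CPM. Of these, batch 1 pGal 2 and batch 1 OVA 1 stood apart with Cd4 at 197 and 164 CPM, against a median of 1.95 CPM. Both were kept in the OT-I comparisons, and whether CD4 cells were among them was not tested. In the 14 labelled OT-II, Cd4 lay between 248 and 1125 CPM and Cd8a between 0.331 and 118 CPM. Of the therapeutic libraries, 22 labelled OT-I had Cd8a of 701 to 1413 CPM and Cd4 of at most 4.78 CPM, and 20 labelled OT-II had Cd4 of 285 to 1359 CPM and Cd8a of at most 13.7 CPM. The other 11 carried the lineage genes of the other cell type. The libraries labelled OT-I OVA 6 and 8, OT-I pGal 5 and 7, and OT-I saline 3 and 6 had Cd4 of 424 to 1373 CPM and Cd8a of at most 2.72 CPM. The libraries labelled OT-II OVA 6 and 8, OT-II pGal 5 and 7, and OT-II saline 3 had Cd8a of 799 to 1271 CPM and Cd4 of at most 4.12 CPM. They were kept under their labels. Therapeutic values are given both for all libraries as labelled and for the 42 matching libraries, and genes are named from the matching libraries unless said otherwise.

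**Figure D1:**
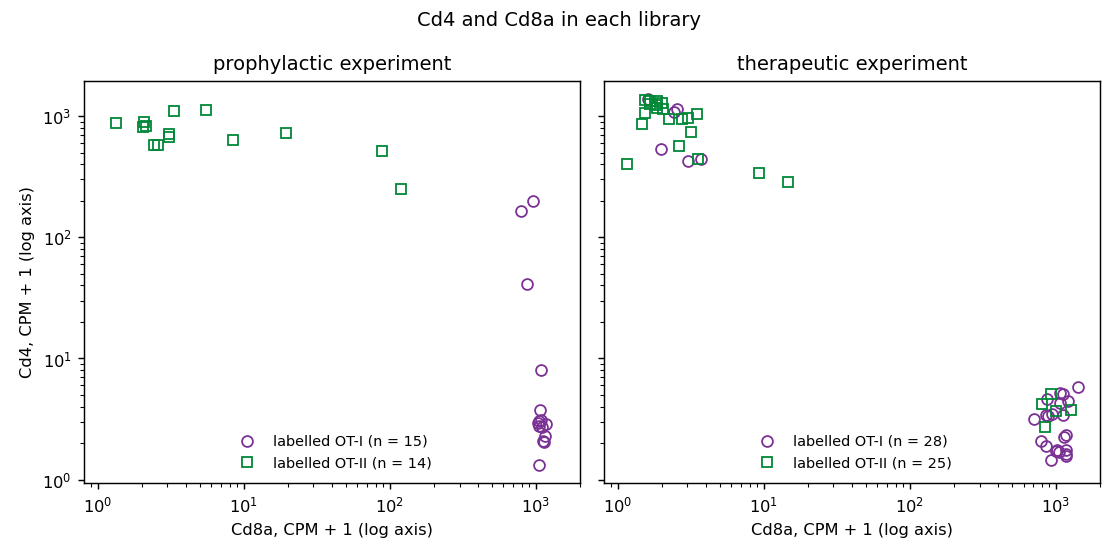
Cd8a (horizontal axis) against Cd4 (vertical axis) in each library of the prophylactic (left) and therapeutic (right) experiment, as CPM + 1 on log axes; each point is a library, circles are labelled OT-I and squares OT-II. In the right panel 6 circles lie with the squares, at Cd4 of 424 to 1373 CPM, and 5 squares with the circles, at Cd8a of 799 to 1271 CPM.

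Whether glycosylated and plain antigen leave CD4 T cells in different states was addressed by comparing pGal with OVA in OT-II cells of the prophylactic experiment. After pGal these cells had more transcripts of the inhibitory receptor genes Ctla4 and Lag3 and of some genes linked to T cell unresponsiveness, and fewer of Il7r, Dntt and Ly6c1. Ctla4, which encodes an inhibitory receptor that competes for costimulatory ligands, rose from 47.5 ± 18.8 CPM (SD, n = 4) after OVA to 177 ± 52.0 CPM (SD, n = 5) after pGal. Izumo1r, encoding folate receptor 4, rose from 125 ± 51.2 to 493 ± 181 CPM, and Nrp1, encoding the surface receptor neuropilin 1, from 28.5 ± 2.87 to 95.3 ± 17.2 CPM. Il7r, the receptor for the survival cytokine interleukin 7, fell from 188 ± 35.8 to 102 ± 27.8 CPM. Dntt, the DNA polymerase that adds nucleotides at antigen receptor joints in developing lymphocytes, fell from 44.5 ± 23.9 to 3.66 ± 1.43 CPM.

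In this comparison 264 of 14128 tested genes were called, 157 higher and 107 lower after pGal. All 33 called named genes lay on the same side of the OVA mean of the batch in each of the 5 pGal libraries. For 32 of them the pGal and OVA libraries did not overlap. These genes were picked from the called ones in the same libraries. Such tallies, here and in the comparisons below, therefore follow largely from the choice and add no support. In the list of inhibitory receptors and exhaustion, 5 of 20 measured genes rose and none fell over all genes, and adjusted over the list alone 10 rose and 1 fell. Among its risen members were Ctla4 (log2 fold change 1.90, SE 0.291, adjusted p = 0.00794), Cd200, a ligand that restrains myeloid cells (1.65, SE 0.221, adjusted p = 0.00465), and Lag3, an inhibitory receptor for MHC class II (1.73, adjusted p = 0.0380). Nfatc1, a transcription factor of antigen receptor signalling (0.58, adjusted p = 0.0195), rose as well. Pdcd1, encoding PD-1, was at 67.0 ± 27.1 CPM after pGal and 29.9 ± 8.49 CPM after OVA and was not called (log2 1.16, adjusted p = 0.0881). Neither were Tigit (-1.57, adjusted p = 0.142) and Tox (0.68, adjusted p = 0.199). The list as a whole rose by camera (adjusted p = 8.43e-05), with adjusted p = 0.0709 with an estimated correlation.

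The anergy list had 3 risen and no fallen genes of 18 over all genes, and 5 and 0 adjusted over the list alone. They were Izumo1r (log2 1.96, SE 0.307, adjusted p = 0.00866), Nrp1 (1.75, SE 0.176, adjusted p = 0.00136) and Rgs1, a regulator of G protein signalling (1.17, adjusted p = 0.00637). Its camera adjusted p was 0.0418, and adjusted p = 0.186 with an estimated correlation. The regulatory T cell list had 3 risen genes of 17, Ctla4, Izumo1r and Nrp1, and 6 adjusted over the list alone (camera adjusted p = 2.34e-04; adjusted p = 0.0709 with an estimated correlation). Foxp3, the defining transcription factor of regulatory T cells, did not pass, at 25.5 ± 10.2 CPM after pGal and 24.4 ± 10.0 CPM after OVA (log2 0.10, adjusted p = 0.942). The T follicular helper list had 3 risen genes of 15, Cd200, Slamf6 and Maf, and 7 adjusted over the list alone, with a camera adjusted p of 8.43e-05 and adjusted p = 0.0709 with an estimated correlation. In the apoptosis list of 20 genes, Bcl2a1b, a survival factor, was among those that rose (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.0709 with an estimated correlation). By fry's directional test these 5 lists also moved one way, with adjusted p between 0.00219 and 0.00428.

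Of 18 naive and memory genes, Slamf6 and Dapl1 rose and Il7r and Ccr9, a receptor of gut homing, fell, and adjusted over the list alone 3 rose and 4 fell. Its median log2 fold change was -0.12 (camera adjusted p = 0.562, fry mixed adjusted p = 9.74e-06). Among 25 homing and adhesion genes Cd44 (0.89, adjusted p = 0.00794) and Itgb1 (0.63, adjusted p = 0.0273) were in the 3 that rose, and Ccr9 (-2.43, adjusted p = 0.0209) and Gpr183 (-0.58, adjusted p = 0.0118) fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.562). Gbp2 and Gbp7, guanylate-binding proteins induced by interferon, fell by 0.50 and 0.65 on the log2 scale among 29 interferon-stimulated genes (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.562). Cholesterol synthesis genes were lower as a list (median log2 -0.19, camera adjusted p = 6.54e-04, and adjusted p = 0.221 with an estimated correlation), with Lss called over all 21 genes and 4 lower adjusted over the list alone. None of 35 proliferation genes was called, although camera placed the list lower (adjusted p = 0.00167), with adjusted p = 0.862 with an estimated correlation. Mki67, a marker of cycling cells, was at 23.1 ± 17.5 CPM after pGal and 27.7 ± 19.3 CPM after OVA.

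The largest rises outside the lists were those of Mpp2 (log2 3.59), Slc9b2 (3.14), Synpo (3.09), Ccr10 (3.04), D830030K20Rik (2.91) and Ppic (2.84), with adjusted p between 0.00465 and 0.0487. The largest falls were those of Dntt (-3.58), Ly6c1 (-3.23), Pdlim4 (-2.55), Ccr9, Myo6 (-2.20) and Enpp4 (-2.11), with adjusted p between 0.00223 and 0.0209. Synpo, the gene of an actin-associated protein, went from 7.04 ± 3.43 to 58.7 ± 19.2 CPM. Ly6c1, a surface antigen of subsets of CD4 T cells, went from 225.5 ± 122 to 23.7 ± 10.1 CPM. On GRCm38, Ctla4 (ENSMUSG00000026011) lies on chromosome 1 from 60887000 to 60915832 on the plus strand. Izumo1r (ENSMUSG00000031933) lies on chromosome 9 from 14885814 to 14903949 on the minus strand, and Nrp1 (ENSMUSG00000025810) on chromosome 8 from 128358604 to 128503363 on the plus strand. Il7r (ENSMUSG00000003882) lies on chromosome 15 from 9505788 to 9530176 on the minus strand and Dntt (ENSMUSG00000025014) on chromosome 19 from 41029275 to 41059525 on the plus strand.

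Mitochondrially encoded transcripts were higher after pGal for all 13 genes (median log2 0.60, none called; camera adjusted p = 8.39e-05, adjusted p = 0.628 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.22 (camera adjusted p = 6.54e-04, adjusted p = 0.862 with an estimated correlation). B cell markers had a median of 0.53, with 16 of 17 higher, while camera placed them lower (adjusted p = 0.236). There 1 of the pGal and 1 of the OVA libraries were rich in B cell transcripts. Without the libraries rich in B cell transcripts 592 genes were called. Batch 1 alone gave 370 genes and batch 2 alone, with 2 libraries of each treatment, gave none (edgeR). Over both batches DESeq2 called 914 and limma voom 2258, while edgeR with a replicate block called 49, all of them among the 264. Leaving out single libraries moved the count from 70, without batch 1 OVA 2, to 453, without batch 1 pGal 3, which is rich in B cell transcripts.

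**Figure D2:**
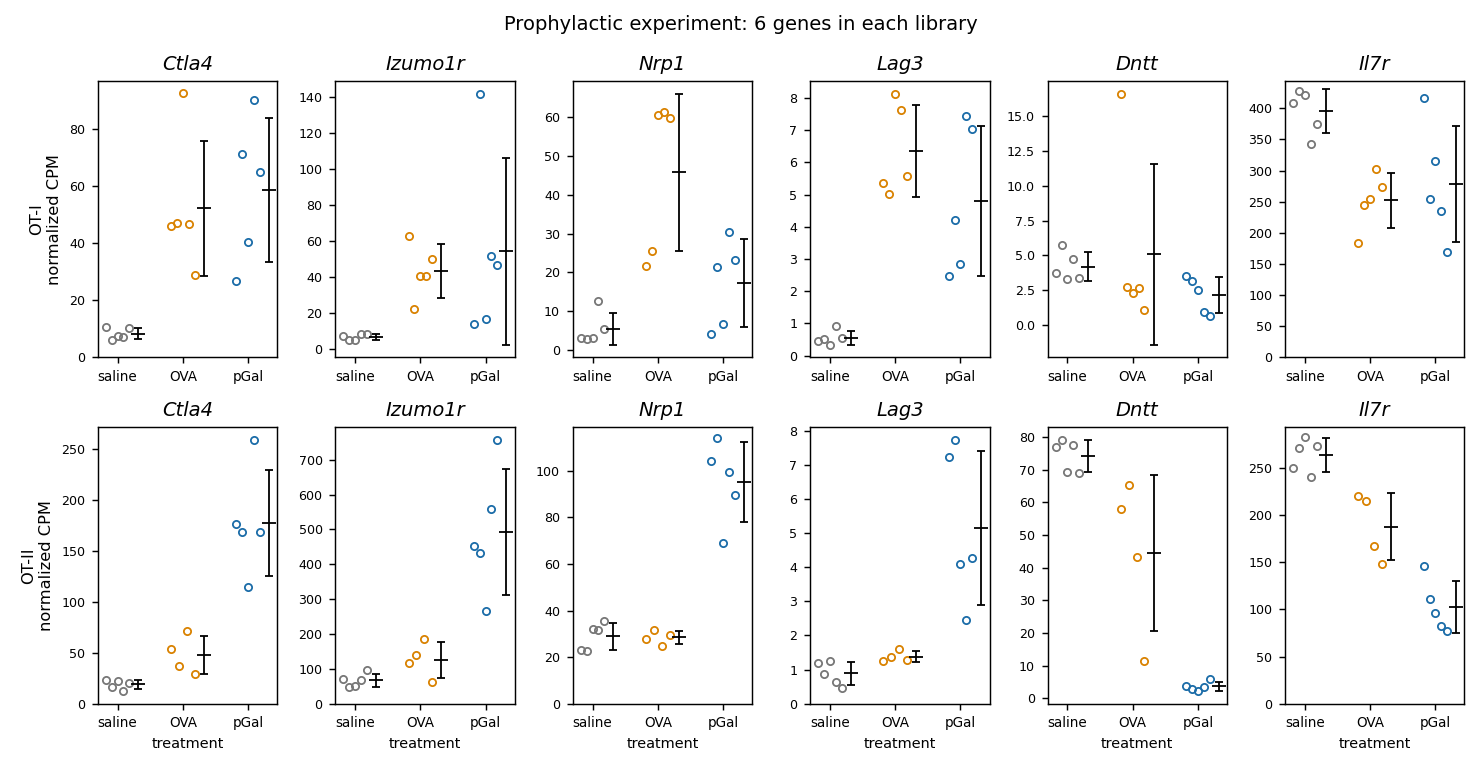
Normalized CPM (vertical axes) of 6 genes in each library of prophylactic OT-I (top) and OT-II cells (bottom) by treatment (horizontal axes); circles are libraries and black bars the mean ± SD. In OT-II cells the 5 pGal libraries lie above the 4 OVA libraries for Ctla4, Izumo1r, Nrp1 and Lag3 and below them for Dntt and Il7r.

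Against saline, pGal changed 1655 genes in prophylactic OT-II cells, 900 higher and 755 lower. Ctla4, Cd200 and Izumo1r had larger fold changes over saline than over plain OVA. The gap is the change of OVA against saline, given below, which passed for Cd200 and not for Ctla4. Ctla4 was at 18.9 ± 4.39 CPM (SD, n = 5) after saline (log2 3.21, adjusted p = 2.40e-05), Cd200 at 22.0 ± 5.98 CPM (2.93, adjusted p = 5.81e-06) and Izumo1r at 66.4 ± 19.6 CPM (2.88, adjusted p = 7.31e-05). Pdcd1 (1.69, adjusted p = 0.00293) and Lag3 (2.55) also rose. So did Tox (0.88, adjusted p = 0.0246) and Tox2 (2.93), transcription factors of exhausted and follicular helper T cells, Cxcr5, the receptor that guides T cells to follicles (3.13), and Il2 (3.23). Wnt10a, a secreted signalling protein, had the highest fold change (5.69), from 1.41 ± 1.00 to 78.2 ± 50.3 CPM. Of 18 naive and memory genes 6 fell and 3 rose (7 and 3 adjusted over the list alone, median -0.24, camera adjusted p = 0.0207, adjusted p = 0.510 with an estimated correlation). Those that fell include Il7r (-1.40), Igfbp4 (-1.39) and Satb1, a chromatin organizer (-1.03, from 1259 ± 45.3 to 620 ± 79.1 CPM). All 66 called named genes moved in 5 of 5 pGal libraries, and for 50 of them the groups did not overlap. Over all genes 10 of 20 inhibitory receptor genes, 7 of 17 regulatory T cell genes and 8 of 15 T follicular helper genes were higher, and 11, 8 and 8 adjusted over the list alone. These 3 lists rose by camera at the preset correlation and also with an estimated correlation (adjusted p = 0.0341 for each). Cholesterol synthesis genes, with Sqle at -1.01, were lower as a list (camera adjusted p = 0.00153, adjusted p = 0.313 with an estimated correlation). Batch 1 alone gave 1740 genes and batch 2 alone none, where edgeR had 2 pGal and 2 saline libraries.

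Plain OVA changed 23 genes against saline in these cells, 22 higher and 1 lower. Cxcr5 rose (log2 2.87, adjusted p = 0.0322), as did Wnt10a (2.89), and Eomes, a transcription factor of effector and memory cells (1.99). Top2a, a topoisomerase of dividing cells (1.71), Cd200 (1.28) and Itgb1 (0.77) rose and Epc1 fell (-0.56), each in 4 of 4 OVA libraries. Ctla4 (1.30, adjusted p = 0.122), Mki67 (2.39, adjusted p = 0.103) and Il7r (-0.48, adjusted p = 0.327) did not pass. The inhibitory receptor list (1 of 20 higher, 6 adjusted over the list alone) and the T follicular helper list (2 of 15, and 3 adjusted over the list alone) rose with a preset and with an estimated correlation (adjusted p = 0.0475 for both). Proliferation genes were higher as a list (median log2 1.19, 13 of 35 adjusted over the list alone, camera adjusted p = 1.22e-22), with adjusted p = 0.139 with an estimated correlation. B cell markers were higher for all 17 genes (median 2.35, camera adjusted p = 0.199) and NK cell markers for all 11 (median 1.89, camera adjusted p = 0.0304, adjusted p = 0.833 with an estimated correlation). Of the libraries compared, batch 2 OVA 2 (Cd79a at 1388 CPM) and batch 2 saline 1 (168 CPM) are rich in B cell transcripts. Without the libraries rich in B cell transcripts 18 genes were called, 12 of them among the 23. Whether other cells contribute to the rises named here was not tested. Either batch alone gave 0 genes with edgeR, and leaving out single libraries 6 to 28, while over both batches DESeq2 called 146 and voom 153. With a replicate block edgeR called 0 genes, so none of the 23 was kept.

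In OT-I cells of the prophylactic experiment, where the same question was asked of CD8 T cells, both antigens raised effector, inhibitory receptor and cell cycle genes over saline, and edgeR called no gene between them over both batches. Gzmb, encoding the cytotoxic protease granzyme B, rose from 8.45 ± 3.45 CPM (SD, n = 5) after saline to 62.6 ± 42.6 CPM (n = 5) after OVA (log2 3.01, adjusted p = 0.00391). It stood at 24.8 ± 18.6 CPM after pGal, where it was not called (1.51, adjusted p = 0.101). Lag3 rose from 0.555 ± 0.221 to 6.35 ± 1.42 CPM after OVA (3.58, adjusted p = 3.48e-05) and to 4.80 ± 2.33 CPM after pGal (3.05, adjusted p = 2.50e-04). Ctla4 rose from 8.35 ± 1.95 to 52.1 ± 23.7 and 58.6 ± 25.1 CPM, and Pdcd1 from 4.20 ± 0.755 to 29.6 ± 8.38 and 19.0 ± 11.9 CPM. Zbtb32, a transcriptional repressor induced in activated lymphocytes, rose by log2 4.68 after OVA and 3.58 after pGal.

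OVA changed 744 of 13802 genes against saline (568 higher, 176 lower) and pGal 463 (365 higher, 98 lower). Among 35 proliferation genes 25 rose after OVA, 30 adjusted over the list alone, with Mki67 at log2 2.44, and 17 rose after pGal, 26 adjusted over the list alone, with Mki67 at 1.73. Of 26 cytotoxic effector genes 12 rose after OVA (17 adjusted over the list alone), among them Gzmk (4.83), Tbx21, a driver of effector differentiation (2.04), and Ifng, the effector cytokine interferon gamma (2.05). After pGal 8 rose (14 higher and 1 lower adjusted over the list alone). Of 20 inhibitory receptor genes 10 rose after OVA and 8 after pGal (12 and 11 adjusted over the list alone). The camera adjusted p after OVA were 1.44e-24 for proliferation, 2.83e-15 for cytotoxic genes and 2.69e-11 for inhibitory receptors, and with an estimated correlation adjusted p = 0.114, 0.105 and 0.0661. After pGal they were 2.45e-17, 5.71e-08 and 7.35e-11, with adjusted p = 0.313, 0.313 and 0.0717 with an estimated correlation. Itgb1, an integrin chain of antigen-experienced cells, rose from 133 ± 25.7 to 1047 ± 343 CPM after OVA, and Myc fell after both (-0.47 each). All 51 and 43 called named genes moved in 5 of 5 libraries of the antigen, and for 37 and 28 of them the groups did not overlap. B cell markers had medians of -1.14 and -1.39 after OVA and pGal, with none called (camera adjusted p = 0.216 and 0.0104, for pGal with adjusted p = 0.717 with an estimated correlation). Batch 1 alone gave 637 genes for OVA and 26 for pGal, and batch 2 alone 19 and 331; without the libraries rich in B cell transcripts the counts were 488 and 209. Leaving out single libraries gave 316 to 888 genes for OVA and 102 to 515 for pGal. With a replicate block the counts were 494 and 242.

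Between pGal and OVA edgeR called 0 genes in these OT-I cells, with 420 at an unadjusted p under 0.05, while DESeq2 called 1 and limma voom 0. The genes with the smallest p were Cx3cr1, a receptor of effector CD8 T cells, at 5.68 ± 1.07 CPM after pGal and 14.9 ± 7.92 CPM after OVA (-1.35, adjusted p = 0.531). Pigo (-0.35) and Vdac1 (0.61) followed, with adjusted p = 1 each. Cytotoxic effector genes stood lower after pGal as a list, with 22 of 26 at a negative fold change, a median log2 of -0.42 and 3 lower adjusted over the list alone (camera adjusted p = 1.37e-09; adjusted p = 0.486 with an estimated correlation). Proliferation (median -0.20, camera adjusted p = 3.40e-07), T helper 1 (-0.19, 0.00153) and cholesterol synthesis genes (-0.10, 0.0446) were also lower, with adjusted p = 0.860, 0.486 and 0.860 with an estimated correlation and no gene called. Fry called no list (smallest adjusted p = 0.8286). In batch 2 alone the cytotoxic effector, proliferation and T helper 1 lists turned to the other direction (camera adjusted p = 0.148, 5.65e-04 and 0.861). Within batch 1 edgeR called 4 genes and within batch 2 none.

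With the libraries taken as independent, the difference between pGal and OVA itself was called as different between OT-II and OT-I cells for 77 of 14845 genes in the prophylactic experiment, 54 with a higher difference in OT-II cells and 23 with a lower one. Nrp1 had the smallest p, with a pGal effect 3.27 higher in OT-II cells on the log2 scale (SE 0.494, adjusted p = 0.00996). Its means in OT-I cells were 17.2 ± 11.3 CPM after pGal and 45.8 ± 20.3 CPM after OVA. Ppic, a cyclophilin, followed (2.68, SE 0.431, adjusted p = 0.0126), and Atp1b1 (-1.57), Enpp4 (-1.998) and Dusp6, a phosphatase of ERK signalling (0.90), had adjusted p = 0.0136 each. OT-I and OT-II libraries of the same treatment and number may come from the same mice, and with a replicate block for them edgeR called 33 genes, Nrp1, Ppic and Dusp6 among them and Atp1b1 and Enpp4 not. Without the filter on low counts it called 48, and without the libraries rich in B cell transcripts 283, while DESeq2 called 280 and voom 931. Chance is not excluded for the count of 77, since 4 of 50 splits of the libraries, the real one included, gave as many genes.

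**Figure D3:**
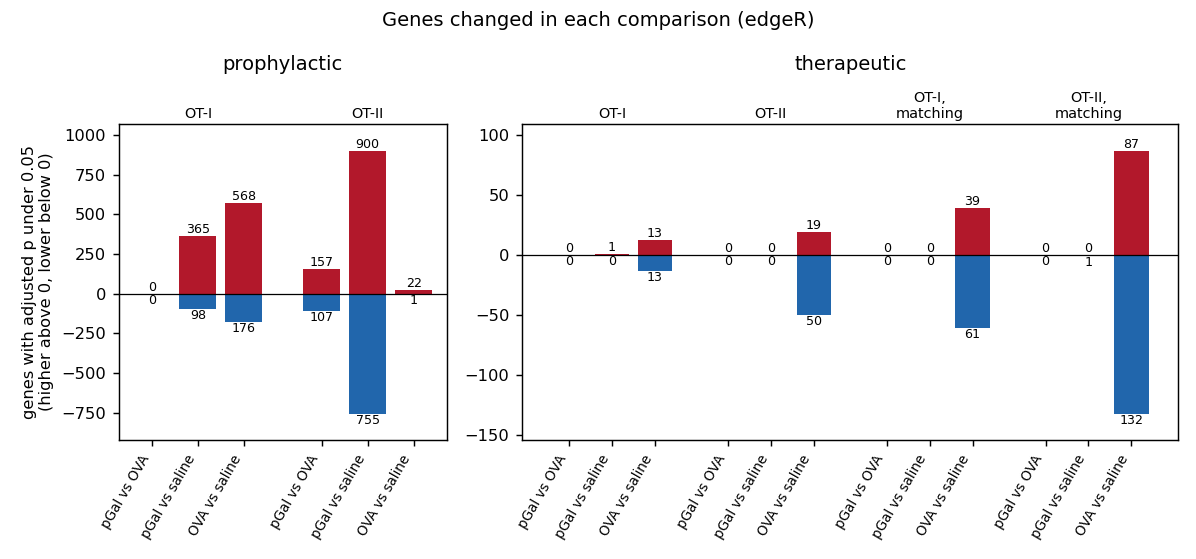
Genes with an adjusted p under 0.05 by edgeR (vertical axis, number of genes) in each comparison (horizontal axis); bars above 0 count genes higher and bars below 0 genes lower in the first-named treatment. The tallest bars are those of pGal against saline in prophylactic OT-II cells, 900 higher and 755 lower.

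In the therapeutic experiment, which asks what the antigens do to T cells already primed by immunization, the comparison with the most genes called by edgeR was that of plain OVA with saline in OT-II cells. Voom called more for OVA against saline in OT-I cells, with 2853 against 845 genes in the matching libraries. In the matching libraries Tox2 rose from 62.0 ± 33.7 CPM (SD, n = 6) after saline to 360.4 ± 142 CPM (n = 6) after OVA (log2 2.54, adjusted p = 0.00593). The inhibitory receptor gene Tigit rose from 12.4 ± 5.20 to 67.9 ± 30.8 CPM (2.46, adjusted p = 0.0105). Pdcd1 rose from 81.2 ± 21.6 to 260.5 ± 126 CPM (1.68, adjusted p = 0.0170) and Cxcr5 from 108 ± 44.0 to 380.2 ± 127 CPM (1.81, adjusted p = 0.0101). Il7r fell from 392 ± 124 to 137 ± 42.0 CPM (-1.52, adjusted p = 0.00768) and Ifng from 74.4 ± 60.8 to 14.8 ± 10.8 CPM (-2.32, adjusted p = 0.0239). The means after pGal (n = 8) were 31.5 CPM for Tigit, 164 CPM for Pdcd1, 205 CPM for Il7r and 30.2 CPM for Ifng, and none of these was called for pGal against OVA or saline.

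Here 219 genes were called for OVA against saline, 87 higher and 132 lower, and with all libraries as labelled 69 (19 and 50). Of those 69, 64 were also called in the matching libraries, all with the same sign. Leaving out single libraries gave 64 to 280 genes (18 to 171 with all libraries), and leaving out those with many genes detected or a high mitochondrial share 118. With a replicate block 47 genes were called in the matching libraries, 45 of them among the 219. All 29 called named genes moved in 6 of 6 OVA libraries, and for 15 of them the groups did not overlap. T follicular helper genes had 5 risen members of 15, 8 adjusted over the list alone, among them Tox2, Cxcr5, Pdcd1 and Il4, a cytokine of helper cells (2.38), with a camera adjusted p of 6.07e-09 and adjusted p = 0.107 with an estimated correlation. Of 17 regulatory T cell genes 4 fell and 1 rose (6 lower and 1 higher adjusted over the list alone). The fallen ones were Il2ra, the alpha chain of the interleukin 2 receptor (-2.27), Ikzf4 (-2.01), Tnfrsf4 (-1.36) and Capg (-1.31), while Izumo1r rose (1.13). The list's camera adjusted p was 0.00272, and adjusted p = 0.518 with an estimated correlation. T cell receptor early response genes fell as a list (3 of 24 over all genes, 14 adjusted over the list alone, median -0.91, camera adjusted p = 1.97e-10, adjusted p = 0.145 with an estimated correlation). So did heat shock and sorting stress genes (1 of 15 and 10, median -0.73, camera adjusted p = 1.05e-07, adjusted p = 0.169 with an estimated correlation). Cytotoxic effector genes also fell (3 of 26 and 14, median -1.48, camera adjusted p = 3.93e-06, adjusted p = 0.437 with an estimated correlation), among them Ccl5 (-3.05) and Id2 (-1.37).

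For pGal against OVA in therapeutic OT-II cells edgeR called 0 genes with the matching libraries, with 1013 at an unadjusted p under 0.05, DESeq2 29 and voom 1. With all libraries edgeR called 0 genes too, with 1584 at an unadjusted p under 0.05, DESeq2 8 and voom 1. The smallest p in the matching libraries were those of D830030K20Rik (log2 1.49), Gm3252 (2.70) and Hist1h2bc (1.25), with adjusted p = 0.672 each. Lag3 was at 12.0 ± 5.96 CPM (n = 8) after pGal and 5.18 ± 3.79 CPM (n = 6) after OVA (1.21, adjusted p = 0.672). Regulatory T cell genes were higher as a list (median 0.74, none called) and cholesterol synthesis genes lower (median -0.33, all 20 negative, none called), each with a camera adjusted p of 9.03e-06 and adjusted p = 0.314 with an estimated correlation. NK cell markers were higher for all 11 genes (median 1.09, camera adjusted p = 8.14e-04, adjusted p = 0.314 with an estimated correlation). Against saline pGal lowered 1 gene, Vps37b, a component of endosomal sorting, from 181 ± 32.1 CPM (n = 6) to 88.9 ± 18.5 CPM (n = 8; log2 -1.03, adjusted p = 0.0326), in 8 of 8 pGal libraries. It was called in 5 of 14 fits that left out a library and not without the filter on low counts, where 0 genes were called. With RLE scaling 14 genes were called, 7 higher and 7 lower, and DESeq2 called 169, both with Vps37b, while voom called 12 without it. A replicate block gave 2 genes, also without it, and 8 of 100 splits gave as many genes as the treatments, so chance is not excluded. With all libraries edgeR called 0, with 885 at an unadjusted p under 0.05, DESeq2 18 and voom 9. T follicular helper genes rose against saline as a list (none of 15 over all genes, 11 adjusted over the list alone, camera adjusted p = 5.80e-13, adjusted p = 0.0212 with an estimated correlation). CD8 lineage markers were lower (median -0.58, 3 of 5 adjusted over the list alone, camera adjusted p = 0.00218, adjusted p = 0.0283 with an estimated correlation).

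**Figure D4:**
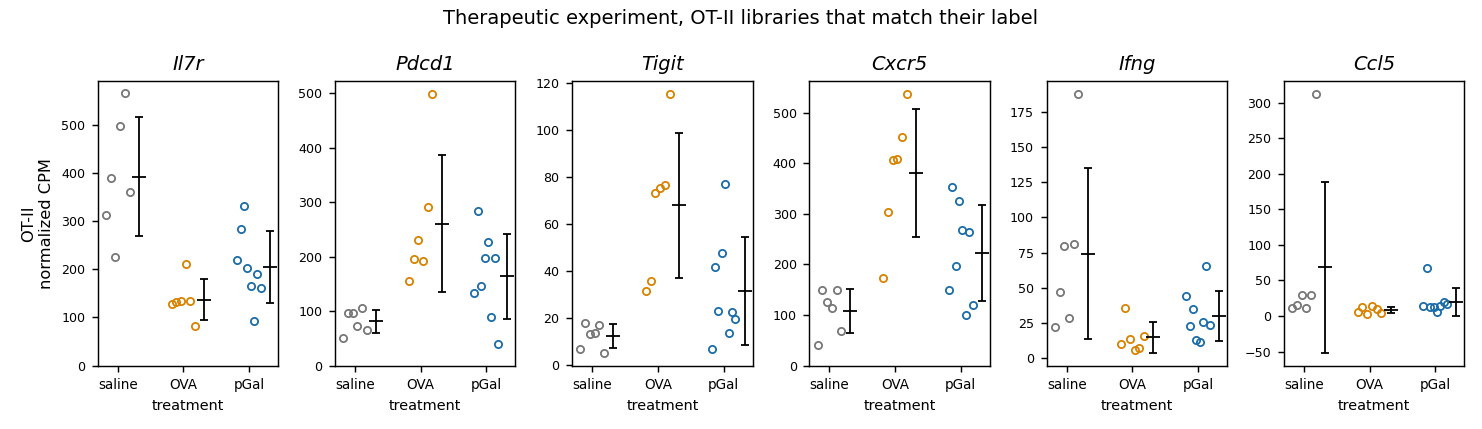
Normalized CPM (vertical axes) of 6 genes in each matching library of therapeutic OT-II cells by treatment (horizontal axes); circles are libraries and black bars the mean ± SD. Il7r, Ifng and Ccl5 are lowest on average after OVA and Pdcd1, Tigit and Cxcr5 highest, with the pGal means between OVA and saline.

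Therapeutic OT-I cells were compared between plain OVA and saline in the same way. In the matching libraries Il7r fell from 717 ± 150 CPM (SD, n = 6) to 216 ± 91.3 CPM (n = 8; log2 -1.73, adjusted p = 7.97e-04). Bcl2, which protects cells from apoptosis, fell from 279 ± 158 to 92.5 ± 39.0 CPM (-1.59, adjusted p = 0.00518), and so did Bbc3, which promotes it (-1.09, adjusted p = 0.0241). Cd40lg, the ligand by which T cells help CD40-bearing cells, fell from 23.7 ± 6.09 to 5.55 ± 2.41 CPM (-2.09, adjusted p = 5.34e-04). Itga4 (1.54), Zbtb32 (1.86), Fhl2 (1.75) and Trp53inp1, a gene induced by p53 (1.06), rose. There were 100 called genes, 39 higher and 61 lower, and 26 with all libraries (13 and 13), of which 15 were shared, all with the same sign. All 17 called named genes moved in 8 of 8 OVA libraries, and for 15 of them the groups did not overlap. Of 20 inhibitory receptor genes 7 rose adjusted over the list alone (median 0.63, camera adjusted p = 1.48e-04, adjusted p = 0.0906 with an estimated correlation). The count was 28 without saline library 5 and 466 without OVA library 10, and without the libraries with many genes detected or a high mitochondrial share it was 1. In this comparison these were OVA 3, 4 and 5, all with many genes detected, and no saline library. Breadth of detection and antigen are thus partly confounded here, and the fit without them also compares fewer libraries. With a replicate block it was 24.

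For pGal against OVA in therapeutic OT-I cells edgeR called 0 genes, with 418 at an unadjusted p under 0.05 in the matching libraries (DESeq2 4, voom 762) and 520 in all libraries (DESeq2 0, voom 262). Cd40lg had the smallest p, at 13.4 ± 3.93 CPM (n = 8) after pGal and 5.55 ± 2.41 CPM (n = 8) after OVA (log2 1.28, adjusted p = 0.445). Cd163l1 (1.73, adjusted p = 0.478) and Cbx7 (0.56, adjusted p = 0.654) followed. CD4 and CD8 lineage markers were higher as lists, the former led by Cd40lg, with adjusted p = 0.0224 and 0.0498 with an estimated correlation and 1 of 5 and 2 of 5 genes adjusted over the list alone. Against saline edgeR called 0 genes in the matching libraries (952 at an unadjusted p under 0.05, DESeq2 20, voom 11). The smallest p were those of Tnfrsf13b (1.07, adjusted p = 0.181), Tstd3 (0.87, adjusted p = 0.181) and Pprc1 (-0.92, adjusted p = 0.306). With all libraries as labelled 1 gene was called, Mospd3, at 74.0 ± 17.2 CPM after pGal (n = 10) and 43.6 ± 4.78 CPM after saline (n = 8; log2 0.76, adjusted p = 0.0435), and RLE scaling gave 2. It was called in 7 of 18 fits that left out a library, and 0 genes were called without the filter on low counts or without the libraries with many genes detected or a high mitochondrial share.

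**Figure D5:**
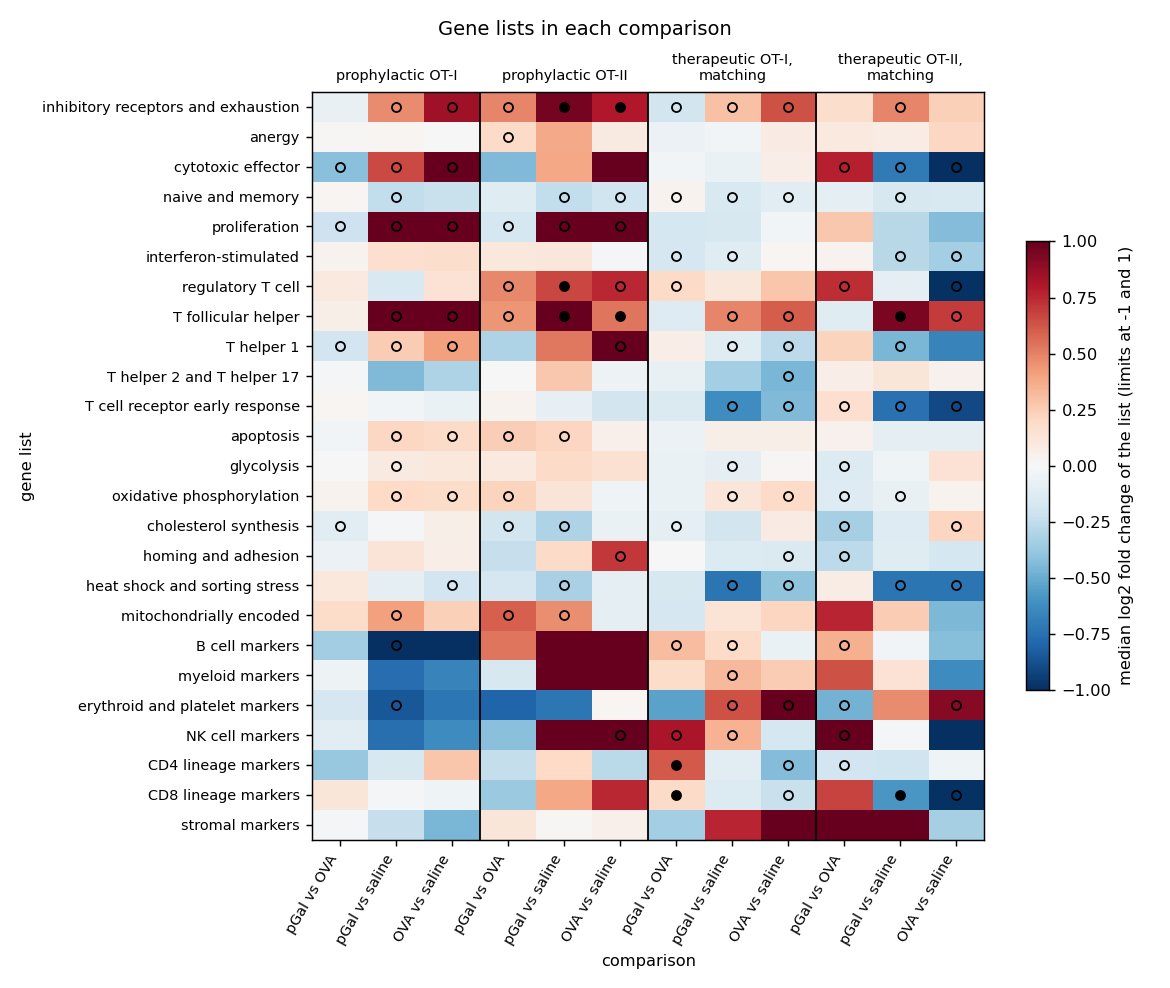
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis) of the prophylactic and matching therapeutic libraries, with the colour scale limited at -1 and 1; open circles mark a camera adjusted p under 0.05 at the preset correlation and filled circles lists that also pass with an estimated correlation. Filled circles stand at 9 list and comparison pairs, 5 of them in prophylactic OT-II cells against saline.

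Whether the effect of pGal against OVA depended on the cell type in the therapeutic experiment was tested in the same way. EdgeR called 0 genes with all libraries (633 at an unadjusted p under 0.05, DESeq2 2, voom 0) and 0 with the matching ones (753, DESeq2 5, voom 2). Cd40lg had the smallest p in the latter (log2 difference -1.77, adjusted p = 0.0952). Between the experiments the effect of pGal against OVA was called as different in OT-II cells for 36 of 15505 genes in the matching libraries, 10 higher and 26 lower in the therapeutic one, and for 6 genes in all libraries (DESeq2 169 and 73, voom 1054 and 976, no filter on low counts 26 and 3). Synpo (-3.05, adjusted p = 0.00149), Tbc1d4 (-1.75), Psen2 (-1.56), Ppic (-2.55) and Smtn (-3.72) were named in the matching libraries. Chance is not excluded for these OT-II counts, with 6 of 50 splits as large for the 36 genes and 11 of 50 for the 6. In OT-I cells edgeR called 0 genes between experiments, with 204 at an unadjusted p under 0.05 in all libraries (DESeq2 9, voom 0) and 283 in the matching ones (DESeq2 2, voom 1). The experiments also differ in the number of mice per library and in the medium the cells were sorted into. Their strain labels differ as well. The label is C57BL/6 in the prophylactic libraries, and in the 53 therapeutic ones its number counts up from library to library. That may be an error of entry, and whether the strains differed is open.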

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

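The tests of exchanged or mixed libraries and of the regulatory T cell share were chosen only after the results they concern were seen, and so were the fits without mismatched libraries, without libraries rich in B cell transcripts and without libraries with many genes detected or a high mitochondrial share.

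The first pattern is that 11 therapeutic libraries hold the lineage genes of the other cell type. A mixture of both cell types is argued against by the labelled type's own marker, which reached at most 0.411% of its median in the matching libraries in any of the 11. An exchange of the OT-I and OT-II libraries of the same treatment and number could account for 10 of them, since in 5 of 25 same-numbered pairs both libraries were out of place, in 1 only the OT-I library and in 19 neither (Fisher's exact test, two-sided, p = 1.13e-04). For OT-I saline 6 such an exchange is excluded, because OT-II saline 6 has a log2 ratio of Cd4 to Cd8a of 8.71, and a single wrong label or an exchange with an outside sample stays open for it. No biological explanation was tested, and whether an exchange occurred at sorting, at library preparation or in the labels is open.

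The second pattern is that 5 prophylactic libraries (batch 1 OT-II pGal 3, batch 2 OT-I saline 1, OT-I OVA 2, OT-II saline 1 and OT-II OVA 2) hold B cell transcripts far above the others, with Cd79a, a part of the B cell receptor, at 96.3 to 1388 CPM and Cd74, abundant in antigen-presenting cells, at 907 to 14564 CPM. A lower share of T cells with all other cells raised alike is argued against, since the lower quartile of the B cell marker shifts lay above the upper quartile of the myeloid, NK, erythroid and stromal marker shifts by at least 1.66 on the log2 scale in all 5. A candidate explanation is B cells among the sorted cells, since 13 further B cell genes outside the list were raised too, with a median of at least 2.88 on the log2 scale in each library. Sorting for OT-I or OT-II cells would remove B cells, and the gate is not given in the sources used here. Myeloid markers were raised in these libraries as well, by medians of 0.885 to 3.79, so other cells stay open beside B cells, and no biological explanation was tested.

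The third pattern is the set of 264 genes that differ between pGal and OVA in prophylactic OT-II cells, with Ctla4, Izumo1r and Nrp1 among the risen ones. B cells in some libraries are argued against as its whole cause, since without the libraries rich in B cell transcripts the genes' log2 fold changes had a median ratio of 1.06 to those with them (quartiles 0.973 and 1.13), all 264 kept their sign and 243 were called. A larger share of Foxp3-expressing regulatory T cells is argued against for the rise of Ctla4, since the 95% interval of the Foxp3 log2 fold change ends at 0.566 and the rise of Ctla4 is 1.90, provided that Ctla4 and Foxp3 keep their ratio in such cells. In batch 1 alone the median ratio was 1.03 with 147 of the 264 called, and in batch 2 alone 0.995 with none called. In batch 2 fewer libraries were compared and OT-II OVA 2 is rich in B cell transcripts, and what sets the loss of calls was not tested. Agreement within a batch is expected in part, since the genes were chosen over both batches. A difference in antigen dose between the treatments was not tested, and a treatment effect on these cells stays open as a hypothesis.

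Single far libraries were looked for in therapeutic groups only, since the prophylactic groups of a batch were too small. Among 108 groups of libraries and measures, 13 held a library far from the others of its group, and chance gives about 1 in 20 groups. In 10 of the 13 that library is one of the 11 with the lineage genes of the other cell type. The library labelled therapeutic OT-II saline 3 stood apart for Cd4 at 4.12 CPM (next 339), Cd8a at 929 (next 8.22), Cd8b1 at 2267 (next 30.2), Gzmb at 466 (next 12.3) and Tox at 39.97 CPM (next 111). The library labelled OT-I pGal 7 had Pdcd1 at 247 CPM (next 90.9) and Foxp3 at 22.1 CPM (next 4.25), and that labelled OT-I OVA 6 had Foxp3 at 15.4 CPM (next 2.49). Ifng was 299.7 CPM in the library labelled OT-II pGal 7 (next 65.2). The mitochondrial share was 7.93% in the library labelled OT-I pGal 5 (next 1.28%). Of the libraries that match their labels, OT-I OVA 2 had a mitochondrial share of 1.75% (next 1.04%), OT-I pGal 3 a total of 56.7 M counts (next 44.1) and OT-II pGal 9 had 19565 genes detected (next 16958). A test for single far libraries can miss 2 that stand apart together, as did OT-II pGal 5 and 9 with mitochondrial shares of 9.08% and 7.31%.

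Tests of the difference itself picked out the following genes. In the prophylactic experiment the log2 fold change of pGal against OVA was higher in OT-II than in OT-I cells by 3.27 for Nrp1, 2.68 for Ppic and 0.90 for Dusp6. The difference was -1.57 for Atp1b1 and -1.998 for Enpp4, and neither of these was called with the replicate block across cell types. For the count of 77 genes there, 4 of 50 splits were as large (highest other 283), so chance is not excluded. Between the experiments chance is not excluded for the counts in OT-II cells, 6 genes with all libraries (11 of 50 splits as large, highest other 138) and 36 with matching ones (6 of 50, highest other 138). There, with all OT-II libraries as labelled, the therapeutic value minus the prophylactic one was 2.40 for Tubb2a, -3.09 for Gpr55, -1.55 for Psen2, -1.13 for Rgs3 and -0.97 for Daxx, with adjusted p between 0.0272 and 0.0345. With matching libraries it was -3.72 for Smtn, -3.05 for Synpo, -2.55 for Ppic, -1.75 for Tbc1d4 and -1.56 for Psen2, with adjusted p between 0.00149 and 0.00412.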

How the results depend on the processing

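The fits without mismatched libraries, without libraries rich in B cell transcripts, and without libraries with many genes detected or a high mitochondrial share were chosen after the data were seen, and all other alternatives before.

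No named gene value that was called in the main fit or in the alternative changed sign. Values called in neither did, 165 of them when single libraries were left out, 37 with limma voom, 25 with the replicate block, 20 without libraries with many genes or a high mitochondrial share, 16 in batch 1 alone, 15 without mismatched libraries, 13 without libraries rich in B cell transcripts, 12 in batch 2 alone, 10 with DESeq2 and 1 with RLE. Of the named gene values 516 of 522 kept their side of the threshold with RLE size factors, 476 of 507 with DESeq2 (31 stronger), 478 of 522 with limma voom (14 weaker, 30 stronger), 478 of 522 without the filter on low counts (44 weaker). They were 196 of 235 without libraries with many genes or a high mitochondrial share (39 weaker), 226 of 265 without libraries rich in B cell transcripts (33 weaker, 6 stronger) and 114 of 117 without mismatched libraries. They were 187 of 260 in batch 1 alone (72 weaker, 1 stronger) and 100 of 260 in batch 2 alone (160 weaker), where fewer libraries were compared. Leaving out single libraries kept 5476 of 6161 (674 weaker, 11 stronger). Of the list results 443 of 450 were kept with RLE, 400 without the filter and 309 with an estimated correlation, where 141 were weaker, and with fry 336 (110 weaker, 4 stronger). In batch 1 alone 6 list results reversed, in batch 2 alone 4, without libraries with many genes or a high mitochondrial share 5 and without mismatched libraries 2. No library had a total under 0.25 of its table's median, so the alternative without such libraries gave no value. The depth of 21.2 M counts or more per library limits genes of low expression, and the spread between libraries limits the rest. Unless said otherwise the cause of a moved value was not tested.

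With DESeq2, prophylactic OT-I cells gave 1 gene for pGal against OVA, 1153 for pGal against saline and 1356 for OVA against saline, and OT-II cells 914, 2490 and 146. Therapeutic OT-I cells gave 8 genes for pGal against saline and 214 for OVA against saline, and OT-II cells 8 for pGal against OVA, 18 for pGal against saline and 530 for OVA against saline. In the matching libraries the 3 counts were 4, 20 and 371 in OT-I and 29, 169 and 714 in OT-II cells. DESeq2 called 280 genes for the interaction of cell type in the prophylactic, 2 in the therapeutic and 5 in the matching therapeutic libraries, and for the interaction of experiment 9 in OT-I and 73 in OT-II cells, with 2 and 169 in the matching libraries. In simulated data of prophylactic OT-I and OT-II cells DESeq2 called 32 and 37 unchanged genes.

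With limma voom, prophylactic OT-II cells gave 2258, 4108 and 153 genes. Therapeutic OT-I cells gave 262, 5 and 2240, and OT-II cells 1, 9 and 798. The matching libraries gave 762, 11 and 2853 in OT-I and 1, 12 and 845 in OT-II cells. The interactions gave 931 genes for cell type in the prophylactic and 2 in the matching therapeutic libraries, and for experiment 976 in OT-II, 1 in matching OT-I and 1054 in matching OT-II cells. With RLE size factors pGal against saline gave 2 genes in therapeutic OT-I cells and 14 in the matching OT-II libraries.

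Without the filter on low counts, where more genes were tested, therapeutic OT-I cells gave 0 genes for pGal against saline and 8 for OVA against saline, and therapeutic OT-II cells 37 for OVA against saline. In the matching libraries OVA against saline gave 47 in OT-I and 127 in OT-II cells and pGal against saline 0 in OT-II cells. The interaction of cell type gave 48 genes in the prophylactic experiment and that of experiment 3 in OT-II cells.

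In batch 1 alone, with fewer libraries, prophylactic OT-I cells gave 4 genes for pGal against OVA and 26 for pGal against saline, and OT-II cells 0 for OVA against saline. In batch 2 alone OVA against saline gave 19 genes in OT-I and 0 in OT-II cells, and in OT-II cells pGal gave 0 against OVA and 0 against saline. List directions turned in batch 1 OT-I cells for naive and memory genes in pGal against OVA (camera adjusted p = 0.0121), for T cell receptor early response (0.0478) and B cell genes (0.607) in pGal against saline and for mitochondrially encoded genes (4.22e-04) in OVA against saline. In batch 1 OT-II cells they turned for B cell (0.0295) and myeloid markers (0.0260) in pGal against OVA. In batch 2 OT-I cells, pGal against OVA, they turned for cytotoxic effector (0.148), proliferation (5.65e-04), T helper 1 (0.861) and mitochondrially encoded genes (5.65e-04).

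Without the libraries rich in B cell transcripts prophylactic OT-I cells gave 209 genes for pGal against saline and 488 for OVA against saline, OT-II cells 592 for pGal against OVA, and the interaction of cell type 283. Without the libraries with many genes detected or a high mitochondrial share, therapeutic OT-I cells gave 0 genes for pGal against saline and 6 for OVA against saline, and the matching libraries 1 for OVA against saline in OT-I cells and 3 and 118 for pGal and OVA against saline in OT-II cells. With them left out the mitochondrially encoded list turned in therapeutic OT-I cells for pGal against OVA (0.364) and in OT-II cells for pGal against saline (0.00505). In the matching OT-I libraries, pGal against OVA, naive and memory (0.382), T cell receptor early response (3.35e-04) and cholesterol synthesis genes (0.848) turned. Without the mismatched libraries pGal against saline gave 0 genes in OT-I and 1 in OT-II cells, OVA against saline 100 and 219, and the interaction of experiment in OT-II cells 36; the mitochondrially encoded list turned in OT-I cells (0.340) and the CD4 lineage markers in OT-II cells (0.0186), both for pGal against OVA.

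Libraries with the same replicate number did not deviate together across treatments. The residuals of same-numbered libraries of different treatments had a median correlation of -0.0203 over 15 pairs in prophylactic OT-I and -0.0112 over 13 pairs in OT-II cells, and 4 of 15 and 2 of 14 libraries were closest to one of their own number. Across cell types the values hint at pairs, though not every pair was over 0.1. The median was 0.112 over 14 prophylactic pairs (others -0.057), with 7 pairs over 0.1 and 20 of 28 libraries closest to their own number. In the matching therapeutic libraries it was 0.188 over 19 pairs (others -0.031), with 11 pairs over 0.1 and 17 of 38 libraries closest to their own number. With all therapeutic libraries it was -0.00364 over 25 pairs (9 over 0.1, 7 of 50). Per the design text each prophylactic replicate is of OT-I and OT-II cells from 3 pooled mice, and whether equal numbers mark the same mice is not given in the sources used here. A paired fit with a replicate block gave 242 and 494 genes for pGal and OVA against saline in prophylactic OT-I cells, 49 for pGal against OVA and 0 for OVA against saline in OT-II cells. It gave 0 for pGal against saline in therapeutic OT-I cells and 24 for OVA against saline in matching OT-I. It gave 2 and 47 for pGal and OVA against saline in matching OT-II libraries, and 33 for the interaction of cell type in the prophylactic experiment. With a block 405 of 506 named gene values kept their side of the threshold and 101 lost the call. For the interaction of experiment a block could not be fitted.

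Leaving out 1 library at a time left all pGal against OVA counts of 0 at 0. In prophylactic OT-I cells the 463 genes of pGal against saline became 102 without batch 2 pGal 2, 114 without batch 2 pGal 1, 125 without batch 2 saline 2. They became 171 without batch 1 saline 3, 200 without batch 2 saline 1, 304 without batch 1 saline 2 and at most 515. The 744 of OVA against saline became 316 without batch 1 OVA 2, 356 without batch 2 saline 2, 463 without batch 1 saline 3, 490 without batch 2 saline 1 and at most 888. In prophylactic OT-II cells the 264 of pGal against OVA became 70 without batch 1 OVA 2, 95 without batch 1 OVA 3, 113 without batch 1 pGal 1 or 2, 146 without batch 2 pGal 1 and 453 without batch 1 pGal 3. The 1655 of pGal against saline stayed between 1145 and 1661. The 23 of OVA against saline became 6 without batch 1 saline 2 or batch 2 saline 2, 8 without batch 1 OVA 3 or batch 2 saline 1, 10 without batch 1 saline 3, 13 without batch 2 OVA 1 and at most 28. In therapeutic OT-I cells the 1 gene of pGal against saline was lost without pGal 4 or 5 or saline 1, 3, 5, 6, 7 or 8 (0 genes), and 2 were called without pGal 2, 3, 6, 7, 8, 9 or 10. There the 26 of OVA against saline became 6 without saline 4, 7 without saline 5, 8 without OVA 3, saline 1 or saline 8, 9 without OVA 4, 10 without OVA 7, 11 without OVA 6, 12 without OVA 5. They became 16 without saline 6 or 7, 65 without saline 3 and 157 without OVA 10. In therapeutic OT-II cells the 0 of pGal against saline became 1 without pGal 8 or 9. There the 69 of OVA against saline became 18 without OVA 5, 20 without OVA 3 or 4, 24 without OVA 6 or saline 1, 27 without OVA 7. They became 28 without saline 7, 37 without OVA 8, 40 without saline 5, 42 without saline 2 and 171 without saline 3. In the matching OT-I libraries pGal against saline gave 1 gene without pGal 10, and the 100 of OVA against saline became 28 without saline 5, 30 without OVA 4, 41 without saline 1, 43 without saline 8. They became 49 without OVA 3, 50 without OVA 5, 54 without OVA 2, 56 without saline 7, 60 without OVA 7, 151 without OVA 9 and 466 without OVA 10. In the matching OT-II libraries the 1 gene of pGal against saline was lost without pGal 1, 3, 4, 6 or 10 or saline 2, 5, 6 or 7, while 4 were called without saline 1 and 11 without pGal 9. There the 219 of OVA against saline became 64 without OVA 5, 72 without OVA 3, 79 without OVA 4, 87 without OVA 7, 122 without saline 7, 132 without saline 1 and at most 280.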

Other observations

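The tests of other splits of the libraries were set before the results were seen, while the matching libraries they partly run on were defined after the data were examined.

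Single genes of further lists were called for pGal against saline in prophylactic OT-II cells, while the T cell receptor early response, interferon-stimulated and glycolysis lists did not pass camera. Irf4, a transcription factor scaled by antigen receptor signalling, rose from 21.8 ± 10.6 to 74.2 ± 15.1 CPM (SD, n = 5 each), and Bhlhe40 (log2 2.48) and Egr3, a transcription factor induced by calcium signals (1.49), rose too, while Ier2 (-1.10) and Dnajb1, a heat shock cochaperone (-1.09), fell. Of 24 T cell receptor early response genes 4 rose and 3 fell over all genes, and 6 and 6 adjusted over the list alone, so that the median was -0.08 while the mean was 0.26 (camera adjusted p = 0.970, fry mixed adjusted p = 9.13e-08). Among 29 interferon-stimulated genes Oas1a (1.05) and Oas3 (0.88), sensors of double-stranded RNA, were in the 6 that rose, and Gbp2 (-0.80) and Gbp7 (-0.88) in the 4 that fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.752). Of 19 glycolysis genes 5 rose, among them Hif1a, which drives glycolytic genes (0.66), Pfkp (0.60) and Gapdh (0.47), and 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.111). Bcl2a1b (2.10) and Bcl2a1d (2.40), survival factors, rose. The genes named here moved in 5 of 5 pGal libraries, with adjusted p between 1.69e-05 for Bcl2a1b and 0.0160 for Gapdh.

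In pGal against OVA the same cells had no called gene in the lists of glycolysis (19 genes, median log2 0.10, camera adjusted p = 0.562), T helper 2 and T helper 17 (12, median 0.01 and mean -0.02, 0.963), myeloid (18, median -0.16, 0.739), erythroid and platelet (11, median -0.80, 0.0776), NK cell (11, median -0.42, 0.572), CD4 lineage (5, median -0.24 and mean 0.04, 0.712), CD8 lineage (5, median -0.37, 0.711) and stromal markers (4, median 0.12, 0.726), and none in heat shock and sorting stress genes (15, median -0.17, 0.0526), T cell receptor early response (24, median 0.04, 0.667) or cytotoxic effector genes (26, median -0.45, 0.216). Adjusted over the list alone 1 cytotoxic gene rose and 1 fell, 1 heat shock gene fell, and none passed in the other lists. T helper 1 genes had 1 fallen member of 16, Il18r1, a cytokine receptor chain (-1.44, adjusted p = 0.0162), and the same 1 adjusted over the list alone (camera adjusted p = 0.562).

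Other splits of the libraries into groups of the same sizes, within experiment, cell type and batch, were fitted to see whether chance can be excluded. Where the treatments gave 0 genes every split is as large, so the splits cannot tell and only their highest count is given. In prophylactic OT-I cells it is excluded for pGal against saline (463 genes, highest other split 11, 1 of 60 splits as large) and for OVA against saline (744, highest other 4, 1 of 60). For pGal against OVA, with 0 genes, the highest other split gave 0 (60 of 60). In prophylactic OT-II cells chance is excluded for pGal against saline (1655, highest other 3, 1 of 60) and OVA against saline (23, highest other 12, 1 of 60). For pGal against OVA 2 of 60 splits were as large as the 264 genes, a share under the limit set beforehand. The other of these splits gave more genes than the treatments, 380, so the splits do not firmly exclude chance. That split sets batch 1 pGal 3, which is rich in B cell transcripts, with the 4 OVA libraries against the other pGal libraries. In therapeutic libraries as labelled, chance is excluded by the limit set beforehand for OVA against saline in OT-I (26, highest other 0, 1 of 100) and OT-II cells (69, highest other 0, 1 of 100). For OT-I cells this holds only for that set of libraries, which includes mismatched ones. The matching OT-I libraries, given below, do not exclude chance. Without the libraries with many genes detected or a high mitochondrial share, 6 of the 26 genes were called. For pGal against saline in OT-I cells 3 of 100 splits gave as many genes as the treatments, 1 (highest other 1), a count too small to exclude chance by. With 0 genes for the treatments, the highest other split gave 384 for pGal against OVA in OT-I cells, 1 in OT-II cells and 2681 for pGal against saline in OT-II cells (100 of 100 each). The split with 384 genes sets all 4 mismatched libraries of the comparison in one group and that with 2681 all 3, which points to a structure of the samples. In the matching libraries chance is excluded for OVA against saline in OT-II cells (219, highest other 1, 1 of 100). In OT-I cells 4 of 100 splits were as large as the 100 genes of the treatments (highest other 1704). That share lies just under the limit set beforehand, and only 100 of 3003 possible splits were fitted, so it cannot exclude chance. With 1 gene left without libraries of broad detection or high mitochondrial share, which included no saline library, what sets that count stays open. Nor is chance excluded for pGal against saline in OT-II cells (1, highest other 5040, 8 of 100). With 0 genes for the treatments, the highest other split gave 591 for pGal against OVA in OT-I and 0 in OT-II cells, and 0 for pGal against saline in OT-I cells (100 of 100 each). The splits with 591, 1704 and 5040 genes, where the treatments gave 0, 100 and 1, point to a structure of the samples beside the treatments. The split with 1704 genes keeps OVA 3, 4 and 5, which had many genes detected, together with OVA 1, 7 and 9 and saline 2 and 8. The split with 5040 genes sets libraries with Cd4 of 860 CPM or more against those with 734 CPM or less. What these splits follow was not tested.

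For the interactions 50 splits were fitted. For the 77 genes whose pGal effect differs between the cell types in the prophylactic experiment 4 of 50 splits were as large (highest other 283). By the rule set beforehand chance is not excluded. The split with 283 genes keeps every OT-II library in its own group and regroups OT-I libraries only. It still holds the real OT-II difference. For the cell types in the therapeutic experiment, with 0 genes for the treatments, the highest other split gave 1263 and in its matching libraries 1053 (50 of 50 each), with a structure of the samples in both. Between the experiments the highest other split gave 0 in OT-I cells, as did the treatments (50 of 50 with all and with matching libraries). Chance is not excluded there in OT-II cells with all libraries (6, highest other 138, 11 of 50) or matching ones (36, highest other 138, 6 of 50), where the highest splits again point to a structure of the samples.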
